A study of Mus musculus with 26 samples.

How the data were processed

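The libraries come from TRAP (translating ribosome affinity purification) of Drd2-expressing medium spiny neurons of mouse dorsal striatum, with 23 immunopurified and 3 input libraries, as paired-end reads per the file names. The deposited values are counts of reads per gene symbol, 1 library per table, with no normalization. Per the submitters' processing notes, reads were aligned with STAR 2.0.0e to mm10 and counted with HTSeq. The annotation release, the strand setting, the kit and the filters are not given in the sources used here, and neither is the length of withdrawal. Groups were read from the sample titles and library sets from the library numbers in them. In set A the titles mark every library but saline withdrawal replicate 2 as a copy of a lower library number, and that library belongs to set A because its own number falls in the series of those lower numbers. The meaning of the mark is not given in the sources used here, and treating that library as a set of its own was among the settings tried.

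The tables fall into 2 annotations: 10 tables list 32531 genes (all 9 of set B and saline withdrawal set A replicate 2) and 16 list 32657. Symbols found in both (31735) and pairs of old and current symbols (239) gave 31974 joined genes, which held 99.5% to 99.9% of each library's gene counts. The 557 and 683 symbols found in only 1 annotation were left out. The 5 closing entries of each table that name no gene were used only for shares of reads. Reads outside genes are here the uniquely aligned reads that HTSeq assigned to no feature. The feature type and strand setting are not given, so these may include reads in introns or on the other strand. Count tables of libraries of the same group were checked for copies. None of 56 pairs was identical, and the chi-square per degree of freedom between pairs was 12.7 to 284. Same-number libraries of different groups showed no sign of pairing: 25 such pairs had a median residual correlation of -0.11 against -0.019 for 78 other pairs. The others ran from -0.747 to 0.769, so this check could miss a pairing. No block was used in the tests reported.

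Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr, and a quasi-likelihood F test in 1 joint fit of the 23 immunopurified libraries with a term per group and a term for the library set (16910 genes, 6 coefficients, 17 residual degrees of freedom). The contrasts were 6 pairs of groups and the interaction of treatment with withdrawal. Immunopurified and input libraries were compared in a separate fit of the 12 immunopurified libraries of the conditions with an input and the 3 inputs, with condition and library set as terms (15612 genes, 10 residual degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are edgeR's with SE from the test, levels are CPM on TMM-scaled library sizes, intervals are 95%, and log2 CPM used a prior count of 2. Coordinates are from GENCODE release M21 (GRCm38), which was used for no counting. A count of 0 allows up to 3 counts, and such floors and intervals cover counting error only.

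Gene lists (41, for cell types, pathways and quality) were written before the data were examined, as were the tests, the named-gene rule and most other settings tried. The 38 cell type and pathway lists were tested with limma 3.58.1 camera on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation and with fry. Lists of fewer than 3 measured genes were not tested. The 3 lists of quality genes were not tested and are not used here. The genes named are the 10 with the largest fold changes per direction among called genes with a mean of at least 5 CPM and a symbol other than a clone or predicted-gene name (5 per direction for immunopurified against input), the 5 with the lowest p in a direction where fewer than 5 passed, up to 4 members of each list with the lowest p, and Drd2, Adora2a, Penk, Drd1 and Chat in every group. Some genes that these rules select are not reported here.

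Correlations across libraries were tested by permutation (100000 resamples with 10 or more libraries, exact below that), and library measures between groups by exact permutation of the group labels. Principal components were computed on log2 CPM of 11051 genes centred per gene. The fits and list tests were tested on simulated data with 100 genes changed by 2-fold and 100 by 4-fold. For immunopurified against input 2% and 38% of them were recovered. A list shifted by 1.5-fold in the withdrawal comparison had adjusted p = 2.49e-11 by camera with the preset correlation, while 1 other list was called. Simulated genes varied independently, so this does not show how the list test behaves where genes of a list vary together. Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, limma voom with library weights, a replicate block, a score of non-neuronal markers as a covariate, other treatments of the library set, fits of the compared groups alone, and leaving out each library. Chosen after seeing the data were the share of reads outside genes as a covariate, the annotation in place of the set, leaving out the 5 libraries above 50% of reads outside genes, a minimum of 5 CPM in input and immunopurified libraries, and list tests within each set and without each library. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.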

Results

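Messenger RNA bound to ribosomes was measured in indirect-pathway medium spiny neurons, the striatal neurons that carry the D2 dopamine receptor. In Drd2-TRAP mice (line CP101) these neurons make the ribosomal protein Rpl10a fused to a green fluorescent protein, and antibodies against that tag pull their ribosomes out of dorsal striatum. Mice had given themselves saline or cocaine intravenously in long sessions, and the titles divide cocaine mice into those whose intake escalated and those whose intake did not. The 23 immunopurified libraries comprised 3 from saline mice, 4 from non-escalating mice, 2 from escalating mice, 5 from saline mice after withdrawal and 9 from non-escalating mice after withdrawal. Another 3 libraries were made from unpurified input RNA, 1 each from saline, non-escalating and saline withdrawal conditions. Library numbers in the titles, which mark some libraries as copies of lower numbers, form 2 sets. Set A holds all libraries without withdrawal, 2 of saline withdrawal and 4 of non-escalating withdrawal, and set B holds the other 3 and 5. Counts assigned to genes ranged from 3279457 to 19122303 per immunopurified library, with both extremes in set A and 3578445 to 5849243 in set B. The inputs held 5990977 (saline), 11549493 (non-escalating) and 5016587 (saline withdrawal). Nothing in the labels says whether each library comes from a separate animal, so the p-values measure the spread between these libraries.

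Transcripts of D2 neurons were enriched over input by the purification, and transcripts of most other striatal cells were depleted. Drd2, the D2 dopamine receptor itself (chromosome 9, 49340627 to 49408177 of GRCm38), was at 3078 ± 1569 CPM (gene counts scaled to library size, SD, n = 12) in immunopurified libraries and at 479.5 ± 69.8 CPM (SD, n = 3) in inputs, a log2 fold change of 2.79 ± 0.38 (SE). Penk, which encodes the enkephalin precursor (chromosome 4, 4133531 to 4138819), was higher by 1.963 ± 0.31, Ttc12, a neighbour of Drd2, by 2.18 ± 0.36, and Sp9, a transcription factor of developing indirect-pathway neurons, by 2.29 ± 0.46. Adora2a, an adenosine receptor (chromosome 10, 75316877 to 75334784), was higher by 1.57 ± 0.40. Drd1, the receptor that marks the other class of medium spiny neuron (chromosome 13, 54051183 to 54055705), was at 30.6 ± 14.7 CPM (SD, n = 12) against 292 ± 41.3 CPM (SD, n = 3), a log2 fold change of -3.25 ± 0.32. Its companions Tac1, the substance P precursor, and Pdyn, the dynorphin precursor, were lower, at -2.72 ± 0.35 and -2.54 ± 0.52. The fall of Pdyn rests on the saline and non-escalating inputs (83.4 and 71.9 CPM). In saline withdrawal Pdyn was at 8.63 CPM in the input and 10.7 ± 3.3 CPM (SD, n = 5) in immunopurified libraries.

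By cell type, all 11 measured markers of indirect-pathway neurons had positive fold changes and 7 were called higher (median log2 fold change 1.90, camera adjusted p = 1.01e-06, adjusted p = 0.102 with an estimated correlation). Of 10 markers of direct-pathway neurons, 6 were called lower (median -2.20, adjusted p = 6.16e-08, adjusted p = 0.00838 with an estimated correlation). Astrocyte markers fell as a group, with 8 of 14 called lower (list median -2.82, adjusted p = 1.54e-12, adjusted p = 0.00838 with an estimated correlation). Among them were Slc1a2, the main glial glutamate transporter (254 ± 58.3 against 1883 ± 529 CPM), Aldoc at -3.86 and the gap-junction gene Gja1 at -3.98. Myelin genes fell as well, with 12 of 15 called lower (median -2.85, adjusted p = 1.52e-16, adjusted p = 0.0151 with an estimated correlation). They included Cnp at -2.43 and Mbp at -1.93. GABAergic interneuron markers fell by a median of 2.78, with 3 of 7 called (adjusted p = 3.48e-05, adjusted p = 0.0234 with an estimated correlation). Sst, the somatostatin precursor, went from 283 ± 86.1 CPM in input to 14.4 ± 6.39 CPM, and Kit was at -2.78. Adjusted over the list alone, called members numbered 8 of 11 in the indirect-pathway list, 9 of 10 in the direct-pathway list, 11 of 14 astrocyte, 14 of 15 myelin and 6 of 7 GABAergic interneuron markers. These direct-pathway, astrocyte, myelin and GABAergic interneuron calls are the list calls that hold with an estimated correlation, out of all 8 comparisons.

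Further lists fell under the preset correlation alone. Cholinergic interneuron markers had a median of -1.55 (adjusted p = 0.0395, adjusted p = 0.352 with an estimated correlation). Among them Slc5a7, the choline transporter, was called at -2.48 ± 0.43 and Chat, the enzyme that makes acetylcholine, had -1.55 without a call (adjusted p = 0.126). Markers of cortical glutamatergic neurons (median -3.17, adjusted p = 0.000369), microglia (-2.29, 0.000276, with the protease Ctss at -3.66) and the neuropeptide list (-0.93, 0.00049) fell too, each with adjusted p = 0.102 with an estimated correlation. Oligodendrocyte precursor markers (-2.61, adjusted p = 5.85e-05, adjusted p = 0.167 with an estimated correlation) and GABA receptors (-0.39, adjusted p = 0.00411, adjusted p = 0.634 with an estimated correlation) completed the lists that fell.

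Blood vessel markers went the other way. All 13 endothelial and mural markers had positive fold changes, with a list median of 2.97 (adjusted p = 9.99e-05, adjusted p = 0.592 with an estimated correlation). Flt1, a VEGF receptor of endothelium, was at 800.5 ± 677.5 CPM (SD, n = 12) against 47.6 ± 50.3 CPM (SD, n = 3), and Cdh5, the cadherin of endothelial junctions, was higher by 4.06 ± 1.06. The inputs also differed in reads ambiguous between genes (8.61% to 12.82% of unique reads, against 0.94% to 2.85% in immunopurified libraries). Whether such library differences affect these folds was not tested. Interferon and antigen presentation genes rose by a median of 2.46 (list adjusted p = 0.00754, adjusted p = 0.838 with an estimated correlation). Among them Psmb8, an immunoproteasome subunit, was called higher at 6.77 ± 1.72. The 5 called genes with the largest rises were at 0 counts in every input, so their folds are lower bounds against a floor of 3 counts over the 3 inputs together. Ccm2l was at least 653-fold higher, Col27a1, a fibrillar collagen, at least 189-fold, and Pou2af1, a B-cell transcription coactivator, at least 160-fold. H2-Q7, a class I histocompatibility gene whose reads its close relatives may share, was at least 142-fold higher and Parp10 at least 140-fold. The largest falls were in Apln, the apelin precursor (-5.48 ± 0.97), Kcnc2, a potassium channel of fast-spiking cells (-4.92 ± 0.63), Cmtm5 (-4.88), Gpr37 (-4.81), a receptor of oligodendrocytes, and Slc6a11, a GABA transporter of astrocytes (-4.40 ± 0.60). Rpl10a, the gene whose product carries the tag (chromosome 17, 28328471 to 28331033), was at 186 ± 84.3 CPM against 60.2 ± 19.99 CPM (adjusted p = 0.00482), while the list of 77 cytosolic ribosomal protein genes was not called (adjusted p = 0.804).

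In total, edgeR's quasi-likelihood test called 1152 of 15612 genes between immunopurified and input libraries, 559 higher and 593 lower, of which 86 of the higher genes were at 0 in every input. DESeq2 called 2950. The count rests on the 3 inputs. It was 565 without the saline withdrawal input, 614 without the saline input and 241 without the non-escalating input. Without the non-escalating input, calls were lost for Adora2a (1.54, adjusted p = 0.132), Sp9 (1.92, 0.0824), Pdyn (-2.12, 0.146), Kit (-1.84, 0.219), Flt1 (3.45, 0.135), Cdh5 (3.21, 0.102), Psmb8 (6.404, 0.132), Ctss (-3.70, 0.085), Pou2af1 (0.0514), Col27a1 (0.0556), H2-Q7 (0.0964) and Cmtm5 (-5.28, 0.0674). Without the saline input, Adora2a (1.28, 0.126), Sp9 (2.04, 0.0563), Pdyn (-1.96, 0.104), Flt1 (3.80, 0.0962), Cdh5 (4.06, 0.103), Psmb8 (7.81, 0.0959) and H2-Q7 (0.0942) were not called. Without the saline withdrawal input, Psmb8 (6.71, 0.0759), Ctss (-3.25, 0.075), H2-Q7 (0.0532), Cmtm5 (-3.67, 0.1) and Gpr37 (-2.99, 0.133) were not called. Cdh5 also missed the threshold without set B replicate 1 of saline withdrawal (adjusted p = 0.0556). Parp10 lost its call without any 1 of the 3 inputs (0.166 at most) and without any 1 of 8 immunopurified libraries. These were saline replicates 1 (adjusted p = 0.0613) and 4 (0.0649), non-escalating replicate 4 (0.062), and saline withdrawal set A replicates 1 (0.0507) and 2 (0.0545) and set B replicates 1 (0.0689), 2 (0.0667) and 3 (0.0601).

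**Figure D1:**
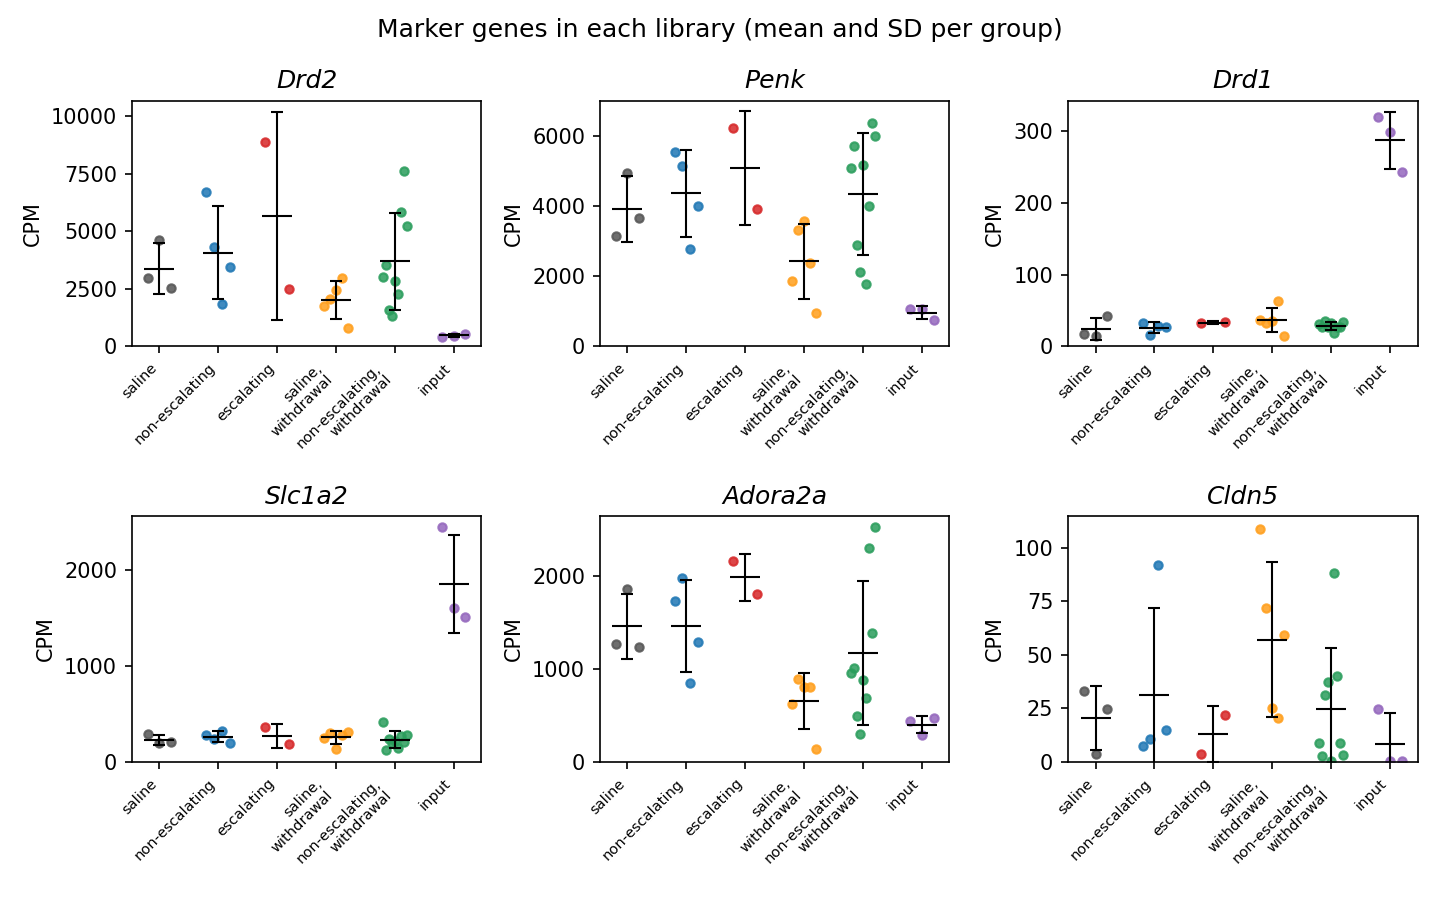
CPM of Drd2, Penk, Drd1, Slc1a2, Adora2a and Cldn5 in each library by group, with the mean of each group as a black line and its SD as bars. Drd1 sits between 14 and 63 CPM in the immunopurified libraries and between 243 and 320 CPM in the 3 inputs.

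Within the immunopurified libraries, the level of D2 neuron transcripts varied widely and moved with the reads assigned to no gene. These are called reads outside genes here, though they may include reads in introns. Drd2 averaged 3380 ± 1100 CPM (SD, n = 3) in saline, 4060 ± 2020 (n = 4) in non-escalating, 5670 ± 4510 (n = 2) in escalating, 2010 ± 816 (n = 5) in saline withdrawal and 3690 ± 2120 (n = 9) in non-escalating withdrawal libraries. Penk followed the same order, from 2420 ± 1070 CPM in saline withdrawal to 5090 ± 1640 CPM in escalating libraries, and Adora2a ran from 653 ± 303 to 1980 ± 253 CPM in the same groups. Drd1 stayed between 24.3 ± 15.8 CPM in saline and 36.5 ± 17.2 CPM in saline withdrawal, and Chat between 4.36 ± 3.13 CPM in saline withdrawal and 14.9 ± 9.14 CPM in escalating libraries. The share of uniquely aligned reads outside genes ran from 21.2% to 70.7% in immunopurified libraries and was 27.3%, 31.6% and 30.8% in the inputs. The first principal component of the 23 libraries held 47.6% of the variance and rose with that share (r = 0.928, rho = 0.927, permutation p = 1e-05 for each, the smallest that 100000 resamples give, adjusted p = 1.6e-05 over 8 relations). Within set A r was 0.973 (n = 15, permutation p = 1e-05), within set B it was 0.782 (n = 8, exact permutation p = 0.0182), and without the 2 libraries farthest from the median share 0.894.

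Vessel and immune transcripts rose with the same share, and neuronal ones fell. The mean level of the endothelial list rose with the share (r = 0.79, rho = 0.865, permutation p = 2e-05 and 1e-05), as did that of the interferon and antigen presentation list (r = 0.839, rho = 0.868, permutation p = 1e-05). The D2 neuron list fell (r = -0.887, rho = -0.884, permutation p = 1e-05), as did the synaptic vesicle list (r = -0.87, rho = -0.829, permutation p = 1e-05 and 2e-05). In set B alone the relations with the D2 neuron list (r = -0.858, exact permutation p = 0.00866) and the synaptic vesicle list (r = -0.813, exact permutation p = 0.013) held, and those with the endothelial list (r = 0.582, exact permutation p = 0.121) and the interferon list (r = 0.695, exact permutation p = 0.0577) missed 0.05. In set A they were -0.94, -0.892, 0.915 and 0.905, and without the 2 farthest libraries -0.843, -0.79, 0.736 and 0.778, in that order. Malat1, a nuclear noncoding RNA, took a larger share of counts along the component (r = 0.848, rho = 0.938, permutation p = 1e-05, 0.903 in set A, 0.719 in set B with exact permutation p = 0.0532, and 0.869 without the 2 farthest). Depth (r = -0.174, rho = -0.195, permutation p = 0.421 and 0.372) and the share of the ribosomal RNA precursor Rn45s (r = -0.133, rho = -0.14, permutation p = 0.541 and 0.522) showed no such relation. For depth r was -0.246 in set A and -0.49 in set B (n = 8, exact permutation p = 0.216). For Rn45s it was -0.238 and 0.166.

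**Figure D2:**
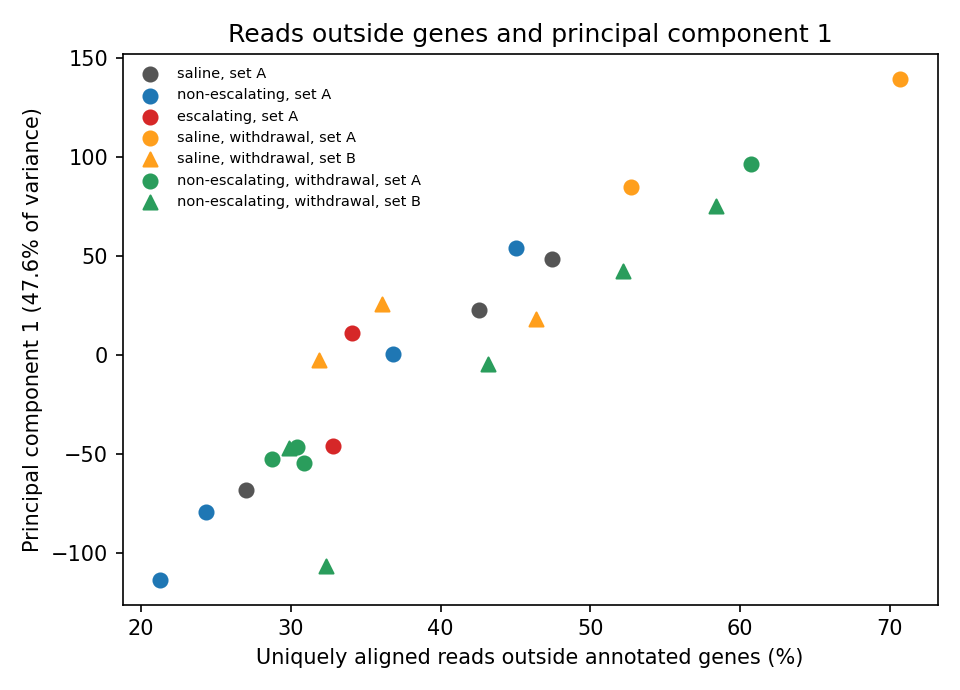
First principal component score of each of the 23 immunopurified libraries (vertical axis) against the percentage of uniquely aligned reads assigned to no gene (horizontal axis). The axis label calls these reads outside annotated genes, though they may include reads in introns. Points are marked by group and library set. The component rises with that percentage in set A (r = 0.973) and in set B (r = 0.782).

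Non-escalating cocaine intake was first set against saline without withdrawal, which asks what cocaine intake changes in these neurons when intake stays stable. Under the preset correlation, the transcripts of energy and protein metabolism were slightly higher as groups. Of 35 splits of these libraries into groups of the same sizes, the real one included, 15 called at least as many lists (8). Nuclear-encoded oxidative phosphorylation genes rose by a median log2 fold change of 0.17 (58 of 79 positive, camera adjusted p = 0.0186) and cytosolic ribosomal proteins by 0.13 (56 of 77, 0.0186). Also higher were heat shock genes by 0.19 (23 of 29, 0.0189), actin and spine regulators by 0.20 (29 of 36, 0.0223) and proteasome subunits by 0.14 (22 of 31, 0.0223). Markers of oligodendrocyte precursors (median -0.59, adjusted p = 0.037), of GABAergic interneurons (-0.33, 0.044) and of interferon and antigen presentation (-0.66, 0.044) fell. Each of the 8 has adjusted p = 0.898 with an estimated correlation, and 0 lists were called with a score of non-neuronal markers as a covariate. Among list members, the proteasome genes Psmd3 (0.71 ± 0.40) and Psma3 (0.55 ± 0.35), the complex I gene Ndufa2 (0.99 ± 0.49), Rps7 (0.97 ± 0.44) and the peptide transporter Tap1 (-2.21 ± 1.45) had adjusted p = 1. No gene passed (edgeR 0 of 16910 genes, 357 at an unadjusted p under 0.05, voom 0), and DESeq2 called 2, both with clone names and near 0 in 1 group. The genes with the lowest p were Rundc1 (2.83 ± 0.85), Ift46, of cilium transport (1.61 ± 0.51), Chaf1a, a chromatin assembly factor (1.80 ± 0.57), Ints2 (1.32 ± 0.43) and the palmitoyltransferase Zdhhc3 (0.99 ± 0.33) on the higher side. On the lower side were Anks6 (-1.81 ± 0.59), Zfp956 (-1.49 ± 0.51), the phosphatase Inpp1 (-2.48 ± 0.89) and Obsl1 (-1.51 ± 0.57), and all of these have adjusted p = 1. Rundc1 was at 2900 CPM in non-escalating replicate 2, and its log2 fold change was 0.14 without that library. The share of reads outside genes was 31.9% ± 11.1 (SD, n = 4) against 39.0% ± 10.7 (SD, n = 3, exact permutation p = 0.371, two-sided, as are all tests here). The number of lists called was 0 without non-escalating replicate 1 or 2, 1 without saline replicate 1 or 4, and 14 without saline replicate 3.

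Escalating intake against saline asks what accompanies intake that escalates. Immediate early genes rose by a median log2 fold change of 0.45 (19 of 27 positive, camera adjusted p = 0.0142, adjusted p = 0.901 with an estimated correlation). Genes of the MAP kinase pathway rose by 0.35 (20 of 21, 0.00847, adjusted p = 0.971 with an estimated correlation). Circadian clock genes rose by 0.39 (14 of 19, 0.00847, adjusted p = 0.692 with an estimated correlation), with Per2 at 190 ± 22.4 CPM (SD, n = 2) against 70.8 ± 11.6 CPM (SD, n = 3) and Per1 at 1.01 ± 0.46. Both escalating libraries had more Per2 (206 and 174 CPM) than any saline or non-escalating library (131 CPM at most). For Egr1 (2540 and 1000 CPM, others up to 1380) and Per1 (428 and 211 CPM, others up to 225) only replicate 1 was above these libraries, and for Dusp1 (239 and 101 CPM, others up to 91.6) both were. Dusp1, a MAP kinase phosphatase, was at 170 ± 97.8 against 75.4 ± 13.9 CPM, and Egr1, an immediate early transcription factor, had 0.89 ± 0.61, with adjusted p = 1 for these 4 genes. Oxidative phosphorylation genes rose by 0.32 (64 of 79, 0.000764) and actin regulators by 0.23 (31 of 36, 0.0402), each with adjusted p = 0.971 with an estimated correlation. GABAergic interneuron markers fell by 0.69 (2 of 9 positive, 0.0331, adjusted p = 0.692 with an estimated correlation).

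Among single genes, Preb, a transcription and secretory-pathway factor (chromosome 5, 30950853 to 30960361), came nearest to a call by edgeR, at 258 ± 289 CPM (SD, n = 2) against 28.9 ± 7.06 CPM (SD, n = 3), a log2 fold change of 3.16 ± 0.56 (adjusted p = 0.144). Its level was 462 CPM in escalating replicate 1 and 53.6 CPM in replicate 2. It was called without replicate 2 (4, adjusted p = 0.00026) and had 0.89 without replicate 1. Ttc27 (chromosome 17, 74717732 to 74863570) showed the reverse, with 4.79 and 566 CPM. Its log2 fold change of 3.76 ± 0.96 was 4.75 without replicate 1 (adjusted p = 0.00684) and -2.14 without replicate 2. Trp53, the p53 tumour suppressor (1.64 ± 0.40), Dhrs1 (1.53 ± 0.39) and Usp27x, a deubiquitinase (1.61 ± 0.43), were above every saline library in both escalating libraries. On the lower side were Gab2, a docking protein of growth factor receptors (-1.59 ± 0.42), the cation channel Trpv2 (-4.07 ± 1.09), Cep85, a centrosome protein (-2.05 ± 0.58), Tbc1d22a (-1.66 ± 0.51) and Tmeff1 (-0.97 ± 0.31). All 9 genes after Preb have adjusted p = 1. EdgeR called 0 genes (518 at an unadjusted p under 0.05), or 2 without either escalating library, voom called 0 and DESeq2 called 6, Preb (adjusted p = 0.000874) and Trpv2 (0.0328) among them. Over all settings tried the adjusted p of Preb ran from 0.00026 to 1. Escalating libraries were deeper (17373355 and 19122303 gene counts) than saline libraries (8666909 to 11449936, exact permutation p = 0.1, the smallest that 2 against 3 libraries allow). The number of lists called was 1 without escalating replicate 1, 3 without saline replicate 1 and 16 without saline replicate 3. With the share of reads outside genes as a covariate it was 1.

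Escalating against non-escalating intake sets the cocaine behaviours side by side. The comparison shares its 2 escalating libraries with the previous one, so like shifts in both are not independent. Immediate early genes rose by a median of 0.59 (19 of 27 positive, camera adjusted p = 0.000973, adjusted p = 0.606 with an estimated correlation), with Dusp1 at 1.13 ± 0.39, Arc, a synaptic plasticity gene, at 1.59 ± 0.84 and Fos at 3.81 ± 1.63 from a very low level. Replicate 1 was above all saline and non-escalating libraries for Arc (162 CPM, others up to 79.7) and Fos (10.7 CPM, others up to 2.51), and replicate 2 was not (51.6 and 1.75 CPM). Interferon and antigen presentation genes rose by 0.65 (15 of 20, 0.00131, adjusted p = 0.993 with an estimated correlation). Usp27x (chromosome X, 7371276 to 7375830) was at 97.2 ± 37.5 CPM (SD, n = 2) against 20.9 ± 6.19 CPM (SD, n = 4), a log2 fold change of 2.22 ± 0.40 (adjusted p = 0.0934). Preb was at 258 ± 289 against 38.5 ± 5.64 CPM, or 2.74 ± 0.50 (adjusted p = 0.0934). Ttc27 (4.20 ± 0.88) and Trp53 (1.77 ± 0.37) had adjusted p = 0.299. Srgap1, a regulator of axon guidance, had 1.38 ± 0.34 with both escalating libraries (395 and 553 CPM) above all 7 others (266 CPM at most). Lower were the fatty acid transporter Slc27a1 (-2.31 ± 0.58), Ints2 (-1.80 ± 0.51), the magnesium transporter Slc41a2 (-1.90 ± 0.55), the transcription factor Casz1 (-1.89 ± 0.59) and Ttc39aos1. The last is an antisense transcript at 0 in both escalating libraries and 11.2 ± 13.8 CPM in non-escalating ones. Circadian Per2 had 1.02 ± 0.42. The genes after Trp53, with Dusp1, Arc, Fos and Per2, have adjusted p = 1. EdgeR called 0 genes (558 at an unadjusted p under 0.05), and voom 0. DESeq2 called 11, among them Usp27x (adjusted p = 0.000401), Ttc27 (0.0032), Preb (0.00331), Ttc39aos1 (0.00406), Trp53 (0.0381) and Slc27a1 (0.0433). Without escalating replicate 1 edgeR called 6 genes, Ttc27 (5.19, adjusted p = 0.000374), Trp53 (2.35, 0.0295) and Usp27x (2.57, 0.0491) among them, and without replicate 2 only Preb (3.59, 0.000357), while Ttc27 turned to -1.70. The number of lists called was 1 without either escalating library and 5 without non-escalating replicate 1. The share of reads outside genes was 33.4% ± 0.884 (SD, n = 2) against 31.9% ± 11.1 (SD, n = 4, exact permutation p = 0.933). Escalating libraries were deeper, with 18.2 ± 1.24 M gene counts (SD, n = 2) against 9.01 ± 2.16 M (SD, n = 4). The exact permutation p was 0.0667, the smallest that 2 against 4 libraries allow.

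After withdrawal, non-escalating cocaine against saline compared 9 with 5 libraries over both sets and asks what persists once intake has ended. Under the preset correlation, neuronal transcripts were higher as groups and vessel and immune transcripts lower. Of 50 splits of these libraries kept within sets, the real one included, 3 called at least as many lists (25). Synaptic vesicle genes rose by a median log2 fold change of 0.59 (29 of 30 positive, camera adjusted p = 8.93e-10), with Snap25, a core fusion protein, at 5519 ± 2018 CPM (SD, n = 9) against 3435 ± 1830 CPM (SD, n = 5) and Sv2b at 0.81 ± 0.29. AMPA, kainate and metabotropic glutamate receptor genes rose by 0.60 (22 of 22, 2.38e-07), with the AMPA receptor partner Cacng3 at 125 ± 45.5 against 57.3 ± 33.9 CPM and the subunit gene Gria3 at 0.69 ± 0.28. NMDA receptor and postsynaptic genes rose by 0.63 (21 of 23, 2.26e-06), with Camk2a at 0.84 ± 0.37. Endothelial and mural markers fell by 1.12 (0 of 13 positive, 1.53e-06), with Vwf at -1.36 ± 0.78 and Cdh5 at -1.17 ± 0.68. Interferon and antigen presentation genes fell by 1.24 (0 of 20, 8.42e-07), with H2-D1 at -1.25 ± 0.70 and Psmb8 at -2.21 ± 0.86. Each of these lists has adjusted p = 0.39 with an estimated correlation, and all the members named have adjusted p = 0.749.

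In all, 25 of 38 lists were called, 20 higher and 5 lower, and none of them with an estimated correlation (lowest adjusted p = 0.39) or by fry (lowest adjusted p = 0.242). The others that rose were calcium and sodium channels (0.52), potassium channels (0.56), pan medium spiny neuron markers (0.61, 17 of 17), axon guidance (0.52), cAMP signalling (0.40), actin regulators (0.43), GABA receptors (0.54), neuromodulator receptors (0.57), neuropeptides (0.55), circadian genes (0.39), MAP kinase genes (0.32), D2 neuron markers (0.58, adjusted p = 0.0123) and mitochondrial ribosomal proteins (0.31), each with adjusted p = 0.39 with an estimated correlation. Oxidative phosphorylation (0.33), proteasome (0.19) and heat shock genes (0.19) rose with adjusted p = 0.518 with an estimated correlation, and cytosolic ribosomal proteins (0.17) with adjusted p = 0.721 with an estimated correlation. Red blood cell (-1.67), astrocyte (-0.35) and microglia markers (-0.67) fell, each with adjusted p = 0.39 with an estimated correlation. The shift was called in set A and mostly not in set B, and the difference between the sets was not itself tested. In set A, with 4 against 2 libraries, 27 lists were called, 24 of them among the 25 and in the same direction. In set B, with 5 against 3, 4 of 36 were called and 12 of the 24 pooled lists that could be tested had the same direction. With an estimated correlation 0 lists were called in either set (lowest adjusted p = 0.397 in set A and 0.876 in set B). Synaptic vesicle genes had a median of 1.61 in set A (adjusted p = 7.17e-11) and 0.02 in set B (0.801), pan medium spiny neuron markers 1.79 and -0.12, and D2 neuron markers 1.59 and -0.14. Endothelial markers fell in both sets, by 1.62 (adjusted p = 0.000161, adjusted p = 0.416 with an estimated correlation) and by 0.58 (0.000518, 0.986 with an estimated correlation). So did interferon genes, by 2.36 (4.59e-07, 0.397 with an estimated correlation) and by 0.29 (0.0438, 0.986 with an estimated correlation). In set B the groups also differed in the share of the ribosomal RNA precursor Rn45s (3.28% ± 1.44, n = 5, against 7.56% ± 0.537, n = 3, exact permutation p = 0.0179). In set A the difference ran the other way (5.84% ± 1.91, n = 4, against 2.97% ± 2.62, n = 2, exact permutation p = 0.2). The share of reads outside genes was 40.7% ± 13.1 (SD, n = 9) against 47.5% ± 15.3 (SD, n = 5, exact permutation p = 0.394). It was 37.7% ± 15.4 against 61.7% ± 12.7 in set A (exact permutation p = 0.2) and 43.2% ± 12.3 against 38.1% ± 7.46 in set B (exact permutation p = 0.571). Without the 5 libraries above 50%, 14 lists were called, and without saline withdrawal set A replicate 1 alone, 16. The 5 include every set A library of saline withdrawal, so the fit without them compares these groups in set B alone.

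The single gene with the lowest p in withdrawal was Lypd1, which encodes a membrane-anchored protein that binds nicotinic acetylcholine receptors (chromosome 1, 125867622 to 125913101). It was at 15.2 ± 4.23 CPM (SD, n = 9) in non-escalating and 6.33 ± 2.67 CPM (SD, n = 5) in saline withdrawal libraries, a log2 fold change of 1.34 ± 0.33. Next came Dlk1, a Notch-related protein (2.70 ± 0.75, with 1 library at 193 CPM), Crcp (0.97 ± 0.27), the cadherin Cdh11 (0.85 ± 0.26) and Gnptg, of lysosomal enzyme targeting (1.29 ± 0.40). Lower were Hip1r (-0.92 ± 0.29), the actin regulator Flii (-1.11 ± 0.36), the membrane protease Adam10 (-0.80 ± 0.26), N4bp2l2 (-0.73 ± 0.24) and the kinase Wnk1 (-0.47 ± 0.16). All 10 genes have adjusted p = 0.749. EdgeR called 0 of 16910 genes (881 at an unadjusted p under 0.05), 0 in set A alone (1667) and 0 in set B alone (223), voom 0, and DESeq2 1, Eps8l3, named here because the count is 1. Among the D2 neuron genes, Penk had 0.92 ± 0.35 and Drd2 0.71 ± 0.45, the latter -0.05 in set B alone.

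**Figure D3:**
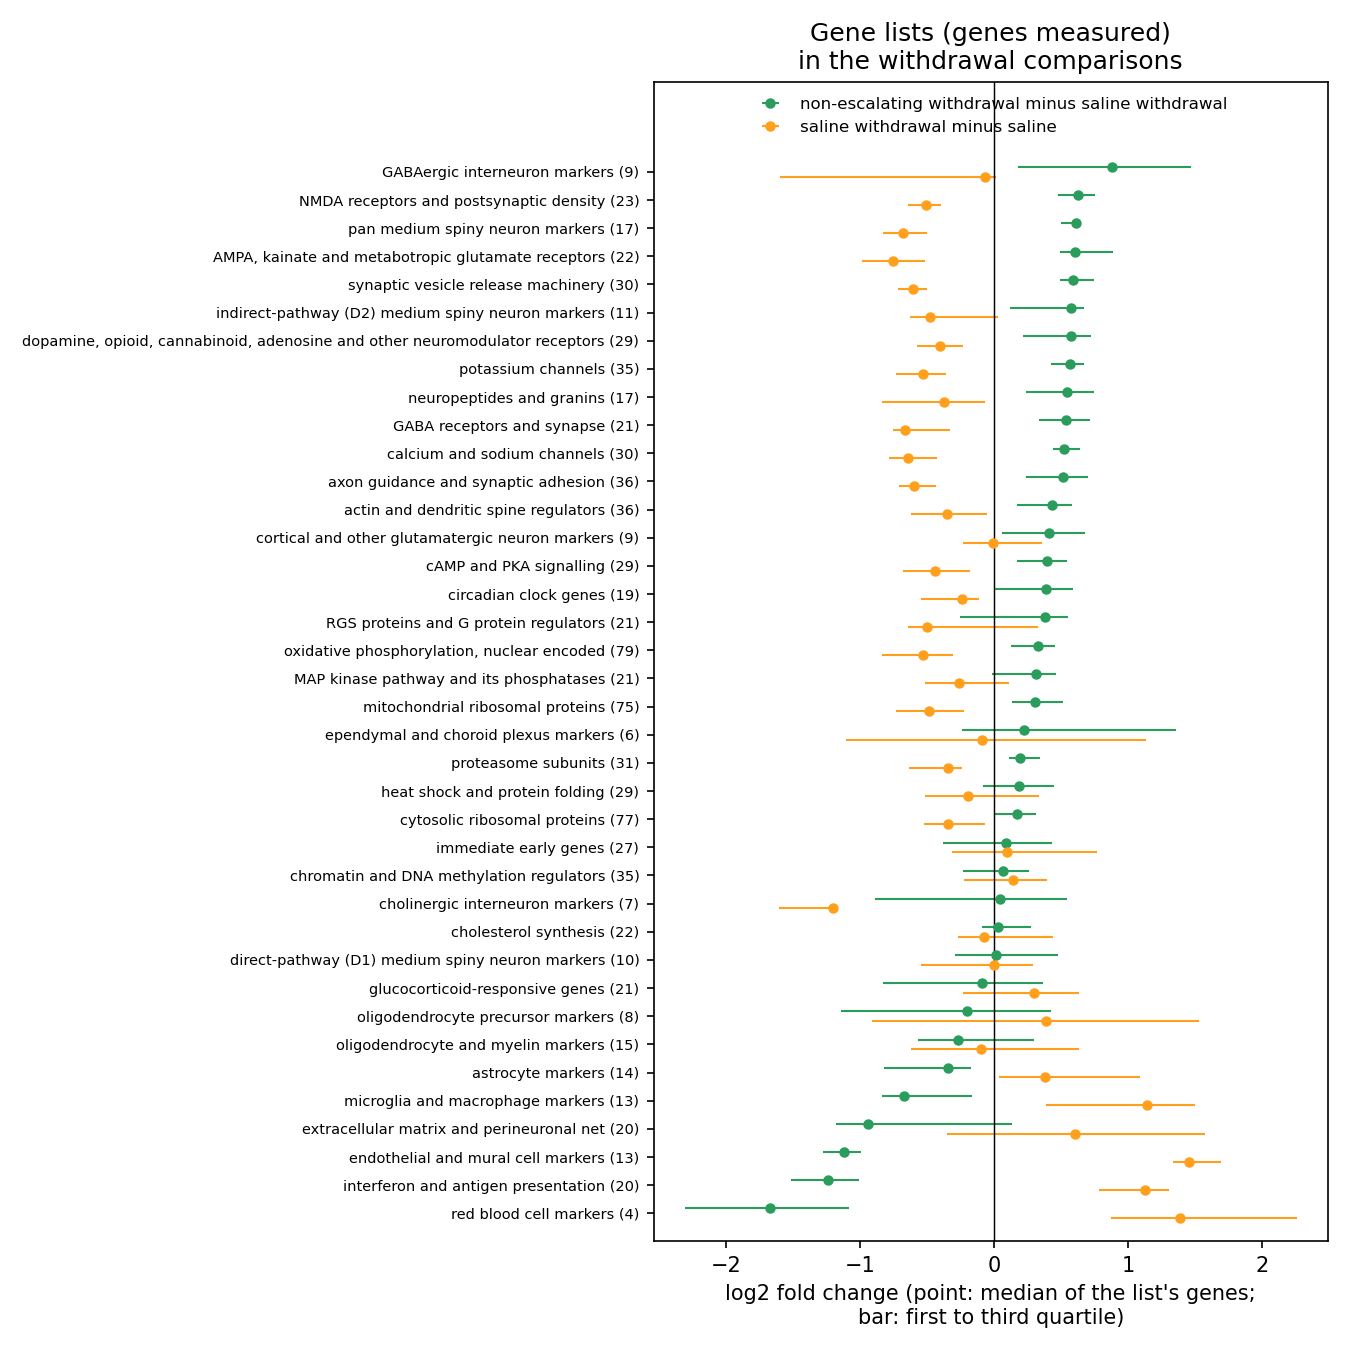
Median log2 fold change (points) and quartiles (bars) of the measured members of gene lists in non-escalating withdrawal against saline withdrawal and in saline withdrawal against saline. The synaptic vesicle list has medians of 0.59 and -0.61 in these comparisons, and the endothelial and mural list -1.12 and 1.46.

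Saline withdrawal against saline asks what time away from self-administration does without cocaine. Set B holds no library without withdrawal, so its libraries enter this comparison through the term for the library set. It shares the saline withdrawal libraries with the preceding comparison, so opposite shifts in the pair are not independent. Under the preset correlation, neuronal and metabolic transcripts were lower as groups and vessel and immune transcripts higher. Of 50 splits of these libraries, the real one included, 15 called at least as many lists (22), and the others called a median of 17. Oxidative phosphorylation genes fell by a median of 0.53 (10 of 79 positive, camera adjusted p = 1.4e-09), synaptic vesicle genes by 0.61 (1 of 30, 2.79e-08) and pan medium spiny neuron markers by 0.68 (0 of 17, 6.9e-07). Gad2, an enzyme of GABA synthesis, was at -0.89 ± 0.41 and the striatal G protein Rasd2 at -0.97 ± 0.59, which turned to 0.23 without the libraries above 50% of reads outside genes. Endothelial and mural markers rose by 1.46 (13 of 13, 2.04e-05), interferon genes by 1.12 (20 of 20, 0.000312), microglia markers by 1.15 (11 of 13, 0.0153) and red blood cell markers by 1.38 (4 of 4, 0.0434). Also lower were calcium and sodium channels (-0.64), AMPA and related receptors (-0.75), potassium channels (-0.53), mitochondrial (-0.49) and cytosolic ribosomal proteins (-0.34), GABA receptors (-0.66), axon guidance (-0.59), cAMP signalling (-0.44), NMDA receptors (-0.50), proteasome (-0.35), neuromodulator receptors (-0.40), cholinergic interneuron markers (-1.20), actin regulators (-0.35), neuropeptides (-0.38) and circadian genes (-0.24). Each of the 22 lists has adjusted p = 0.434 or 0.455 with an estimated correlation.

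Lypd1 was again the gene with the lowest p, at 6.33 ± 2.67 CPM (SD, n = 5) against 24.97 ± 1.82 CPM (SD, n = 3), a log2 fold change of -2.18 ± 0.45. All 5 saline withdrawal libraries (2.49 to 8.88 CPM) were below every other immunopurified library (10.8 CPM at least), in both sets. DESeq2 called it (adjusted p = 0.000531) and edgeR did not (adjusted p = 0.782). Others with adjusted p = 0.782 were Man2b2, a lysosomal mannosidase (1.94 ± 0.50), the Wnt co-receptor Lrp6 (0.88 ± 0.27), Hip1r (1.38 ± 0.43) and the clustered protocadherin Pcdhga8 (1.02 ± 0.32), whose exons are shared within its cluster, on the higher side. The lower side held Rnf7 (-1.41 ± 0.35), the splicing factor Phf5a (-1.60 ± 0.40), Mpp6 (-1.61 ± 0.42) and Crcp (-1.34 ± 0.38). Adnp (chromosome 2, 168180986 to 168207112), a chromatin regulator, had 7.37 ± 1.995, and its level followed the annotation used for counting. It averaged 0.181 CPM in set A libraries counted with the longer annotation and 191 CPM in set B, and was 171 CPM in the 1 set A library counted with the shorter one. EdgeR called 0 genes (885 of 16910 at an unadjusted p under 0.05) and voom 0 (3673 of 16910). The edgeR fit of these groups alone also called 0 (4140 of 14425), so the unadjusted count depends on the model. DESeq2 called 7, of which 3, Adnp (adjusted p = 0.0405), Zfp36 and mKIAA0217, followed the annotation in this way. The last 2 fall outside the naming rule and were chosen after their values were seen. The share of reads outside genes was 47.5% ± 15.3 (SD, n = 5) against 39.0% ± 10.7 (SD, n = 3, exact permutation p = 0.482), and 61.7% ± 12.7 in the set A libraries (exact permutation p = 0.1, the smallest that 2 against 3 allow). Without the 5 libraries above 50%, 9 lists were called, and without saline withdrawal set A replicate 1 alone, 14. The 5 include every set A library of saline withdrawal, so the fit without them has no set in common to these groups. It then rests on the set term.

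Non-escalating withdrawal against non-escalating intake asks the same after cocaine, again with set B entering through the set term. Under the preset correlation, transcripts of energy and protein metabolism were lower as groups. Of 50 splits of these libraries, the real one included, 26 called at least as many lists (13), and the others called a median of 14. Oxidative phosphorylation genes fell by a median of 0.38 (10 of 79 positive, camera adjusted p = 1.25e-12), with Ndufa2 at -1.21 ± 0.41. Cytosolic ribosomal proteins fell by 0.25 (11 of 77, 8.99e-11), with Rps13 at -0.98 ± 0.40, and proteasome subunits by 0.33 (4 of 31, 1.67e-05). Cholinergic interneuron markers fell by 0.76 (2 of 7 positive, 0.00483), with Slc17a8, a vesicular glutamate transporter of these cells, at 4.39 ± 3.39 CPM (SD, n = 9) against 8.61 ± 6.17 CPM (SD, n = 4). Smaller falls were called for mitochondrial ribosomal proteins (-0.18), potassium channels (-0.19), pan medium spiny neuron markers (-0.21), calcium and sodium channels (-0.16), actin regulators (-0.12), cAMP signalling (-0.17), GABA receptors (-0.19), AMPA and related receptors (-0.17) and synaptic vesicle genes (-0.12). Each of the 13 lists has adjusted p = 0.683 with an estimated correlation. Adjusted over the list alone, and not over lists or comparisons, Slc17a8 (-2.47 ± 0.70, adjusted p = 0.0135) and Mvk, mevalonate kinase of cholesterol synthesis (1.80 ± 0.51, 0.0395), passed. The Slc17a8 means above pool both sets, while this fold change comes from the fit with the set term. Its lowest non-escalating withdrawal library was at 0.0746 CPM. The count adjusted over the list alone was 2 against 0 over all genes. In the other 6 comparisons among immunopurified libraries that count was 0 in every list.

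The genes with the lowest p after cocaine withdrawal were Heatr6 (1.22 ± 0.30), the transcription regulators Gtf2ird1 (1.27 ± 0.32) and Maml3 (1.64 ± 0.46), Lurap1 (2.83 ± 0.74) and Mvk on the higher side. On the lower side were the noncoding RNAs Pvt1 (-2.45 ± 0.58) and Particl (-2.25 ± 0.55), Slc41a2 (-1.59 ± 0.39), Ttc30a1, of cilium transport (-3.05 ± 0.78), and Rundc1 (-2.49 ± 0.66), which was 0.21 without non-escalating replicate 2. All 10 have adjusted p = 0.926. Particl overlaps Mat2a on the other strand, and with no strand setting given its reads may not be separable. Pvt1 was at 23.9 CPM in non-escalating replicate 2 (3.29 to 6.29 in the rest of the group). Lurap1 was at 54.4 CPM in non-escalating withdrawal set A replicate 2 (2.52 to 10.9 in the rest). EdgeR called 0 genes (762 at an unadjusted p under 0.05), and voom 0. DESeq2 called 12, among them Heatr6 (adjusted p = 0.022), Gtf2ird1, Lurap1 and Pvt1 (0.0225 each) and Particl (0.0345), and also Zfp36 and mKIAA0217, which followed the annotation. The share of reads outside genes was 40.7% ± 13.1 (SD, n = 9) against 31.9% ± 11.1 (SD, n = 4, exact permutation p = 0.267), or 37.7% ± 15.4 against 31.9% ± 11.1 in set A (exact permutation p = 0.6). The number of lists called was 4 without non-escalating replicate 1, 5 without non-escalating replicate 2 and 4 without non-escalating withdrawal set A replicate 1.

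The interaction asks whether the difference between cocaine and saline was itself different after withdrawal. Neuronal lists were higher and vessel lists lower in it under the preset correlation. Of 50 splits of these libraries, the real one included, 22 called at least as many lists (14). Synaptic vesicle genes had a median of 0.54 (29 of 30 positive, camera adjusted p = 6.16e-05), with Snap25 at 0.90 ± 0.55, and AMPA and related receptors 0.54 (20 of 22, 0.000432), with Cacng3 at 1.12 ± 0.63. Endothelial and mural markers had -0.89 (0 of 13 positive, 0.000969), with Vwf at -1.86 ± 1.38, which was 0.13 without non-escalating replicate 3. In all, 14 lists were called, 11 higher and 3 lower, each with adjusted p = 0.716 with an estimated correlation. The genes with the lowest p were Zfp956 (1.98 ± 0.64), Dlk1 (3.46 ± 1.14), Abcc8, a subunit of ATP-sensitive potassium channels (2.25 ± 0.74), Lypd1 (1.56 ± 0.52) and Anapc16 (1.18 ± 0.39). On the lower side were Ints2 (-1.91 ± 0.53), Dus4l (-3.93 ± 1.14), Aaed1 (-2.56 ± 0.87), Rnf146, a ubiquitin ligase (-1.49 ± 0.51), and Gmeb2 (-1.64 ± 0.57). All 10 and the list members named have adjusted p = 1. EdgeR called 0 genes (345 at an unadjusted p under 0.05), voom 0 and DESeq2 2, both with clone names. The number of lists called was 1 without the libraries above 50% of reads outside genes, 1 without saline replicate 3, 3 without saline withdrawal set A replicate 1, 4 without non-escalating replicate 3 and 9 without non-escalating replicate 4. Removing the libraries above 50% leaves saline withdrawal with set B libraries only.

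How large a change could have been seen differs between the comparisons. Among genes at or above 5 CPM, the median width of the 95% confidence interval on either side of the estimate was 1.67-fold for withdrawal after cocaine against withdrawal after saline, 1.79-fold for withdrawal against none after cocaine, and 1.95-fold for non-escalating intake against saline. It was 2.08-fold for saline withdrawal against saline, 2.12-fold and 2.22-fold for escalating against non-escalating intake and saline, and 2.33-fold for the interaction. In simulated data with 100 changed genes at these sample sizes, a 4-fold change was recovered for 58 genes in the withdrawal comparison, 28 in non-escalating intake against saline and 15 in escalating against non-escalating intake. A 2-fold change was recovered for 11, 0 and 0. Of 113 genes selected for naming, 35 have exons that overlap another annotated gene, 19 of them a protein-coding gene (for example Lypd1 with Gpr39, Dusp1 with Ergic1 and Flii with Llgl1), so their counts are uncertain to that extent. The labels give no strand setting for the counting. Lists for RGS proteins, cholesterol synthesis, chromatin regulators, ependymal markers, extracellular matrix and glucocorticoid-responsive genes were called in none of the 8 comparisons. In tests within 1 set in withdrawal, RGS proteins were called in set A (adjusted p = 0.018, adjusted p = 0.397 with an estimated correlation) and extracellular matrix genes in set B (adjusted p = 0.0387, adjusted p = 0.943 with an estimated correlation).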

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

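All tests of explanations in this part were chosen after their result was seen, except the test of carry-over from other cell types and the counts of splits for the interaction and for immunopurified against input. The list tests with an estimated correlation were planned, and only their use to test an explanation came later.

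The first pattern is the axis that carries 47.6% of the variance between immunopurified libraries, along which reads outside genes, Malat1, vessel and immune transcripts rise and neuronal transcripts fall. The tables argue against depth (correlation with the axis within sets -0.268, at most 0.62 in size at 95%) and against ribosomal RNA (-0.134 for Rn45s). They also argue against carry-over of RNA from all other cell types alike, because per 10 points of reads outside genes the median slope was 0.134 for oligodendrocyte markers (quartiles -0.121 to 0.308) and 0.265 for astrocyte markers, far below 1.02 for endothelial markers (quartiles 0.949 to 1.15). RNA from vessel cells, which the purification should remove (Flt1 at 800.5 CPM against 47.6 CPM in input), RNA from nuclei, or a lower yield of tagged ribosomes may remain as sources, and none was tested apart from the others. A biological difference between groups stays open as untested.

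The second pattern is the 25 gene lists called between non-escalating and saline withdrawal, where neuronal lists rise and vessel and immune lists fall. Of 50 splits of the 14 libraries only the real one, 1 of 50, called as many lists (25, highest other 24), but of 50 splits that kept the numbers of each group in each library set 3 did (highest other 25), so chance was not excluded. The other splits called a median of 14 lists, or 16 when kept within sets. At least 1 list was called by 47 of them, or 48 within sets. The expectation that genes of a list vary together between libraries holds: 0 of the 25 lists were called with an estimated correlation. With reads outside genes as a covariate 3 of the 5 lists that fell were still called and the 5 kept 61.2% to 106% of their median shifts. The astrocyte and microglia lists lost their calls. These calls rest on the preset correlation, and a linear term need not remove all that goes with the share, so the share is not ruled out there. For the 20 lists that rose it cannot be told apart from treatment (15 still called, quartiles of the shift kept 39.4% to 52%, bound 50%). An effect of cocaine stays open as untested, and so does a difference between the sets, where the synaptic vesicle median was 1.61 in set A and 0.02 in set B.

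The third pattern is 7 genes, Adnp, Zfp36 and Setdb2 among them, that are under 0.5 CPM on average in set A libraries counted with the longer annotation and at 5 CPM or more in set B. Gene models that differ between the annotations are a candidate cause: the 1 set A library counted with the shorter annotation lay on the side of set B for 100% of these genes. Adnp, at 7.37 in saline withdrawal against saline, was at 0.39 with the annotation in place of the set, and the other genes were not looked at in that way. No biological explanation was tested.

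For the other comparisons with at least 3 libraries in each group, splits of the same libraries were counted with 35 or 50 splits each. The comparisons of the 2 escalating libraries had no such count. For genes, where the real count was 0 every split gives at least as many by construction, so the splits say nothing about chance. This was 35 of 35 for non-escalating intake against saline (highest other 1), 50 of 50 for non-escalating against saline withdrawal (0), saline withdrawal against saline (0) and the interaction (0). For non-escalating withdrawal against none it was 50 of 50 too, and the highest other split called 4086 genes. That split set 4 libraries with 53.6% of reads outside genes on average, 3 of them of set B, against 9 with 31.1%, 2 of them of set B. The split differs in that share, the library set and the annotation at once, and none was tested as its cause. For immunopurified against input, 50 of 455 possible splits were drawn, and only the real one gave as many genes (1152, highest other 500). That is the smallest share that 50 splits can give, so chance is unlikely here but not excluded. For the number of lists called under the preset correlation, chance was not excluded in the following comparisons. Non-escalating intake against saline had 15 of 35 splits with at least 8 lists (highest other 23, median other 4). Saline withdrawal against saline had 15 of 50 with at least 22 (highest 27, median 17). Non-escalating withdrawal against none had 26 of 50 with at least 13 (highest 26, median 14). The interaction had 22 of 50 with at least 14 (highest 24, median 9). Immunopurified against input had 15 of 50 with at least 13 (highest 25, median 7). No splits were counted for calls with an estimated correlation, so these counts do not address the 4 such lists of immunopurified against input.

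The interaction called 14 lists by a test of the difference between the cocaine effects with and without withdrawal. The medians were 0.45 for pan medium spiny neuron markers, 1.30 for GABAergic interneuron markers, -0.89 for endothelial markers, -2.18 for red blood cell markers, 0.38 for cAMP signalling, 0.54 for AMPA and related receptors, 0.45 for NMDA receptors, 0.46 for GABA receptors, 0.41 for potassium channels, 0.46 for calcium and sodium channels, 0.54 for synaptic vesicle genes, 0.39 for axon guidance, -0.41 for interferon genes and 0.30 for mitochondrial ribosomal proteins. All have adjusted p = 0.716 with an estimated correlation.

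Single libraries stood far from the others of their group in 22 of 155 groups tested. Chance gives about 1 in 20, but most genes tested were chosen for their p in these same libraries, so that rate need not hold for them. Saline withdrawal set A replicate 1 had 14.7 M gene counts (others 3.28 to 4.91), N4bp2l2 at 135 CPM (67.1 to 85.7), Man2b2 at 67.8 CPM (13.4 to 23.7) and Adnp at 0.112 CPM (140 to 194), as the 1 library of its group counted with the longer annotation. Set B replicate 3 of that group had Adam10 at 89.1 CPM (55.4 to 63.3) and Dus4l at 40.0 CPM (3.81 to 7.64). In non-escalating withdrawal, set A replicate 1 had Flii at 152 CPM (14.2 to 51.8), Vwf at 592 CPM (4.32 to 283), Cdh5 at 391 CPM (2.88 to 193) and H2-D1 at 129 CPM (5.52 to 57.9). Set A replicate 2 of that group had Gtf2ird1 at 90.1 CPM (18.0 to 54.5), Lurap1 at 54.4 CPM (2.52 to 10.9) and Maml3 at 85.6 CPM (9.73 to 36.8). Set B replicates 4 and 5 had Adam10 at 70.2 CPM (23.8 to 44.9) and Dlk1 at 193 CPM (1.97 to 20.1). Non-escalating replicate 2 had Rundc1 at 2900 CPM (72.6 to 184), Ints2 at 82.9 CPM (21.3 to 30.9), Pvt1 at 23.9 CPM (3.29 to 6.29) and Dus4l at 23.3 CPM (2.55 to 4.20). Replicate 3 of that group had Vwf at 872 CPM (13.3 to 129), and replicate 4 had Fos at 1.70 CPM (0 in the others) and Arc at 79.7 CPM (15.4 to 24.4).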

How the results depend on the processing

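The covariate of reads outside genes, the annotation covariate, the removal of libraries above 50% of reads outside genes, the minimum of 5 CPM in both kinds of library, and the list tests within sets and without each library were chosen after seeing the data. Removing the libraries above 50% also takes out every set A library of saline withdrawal, so its results mix that share with the library set. The other alternatives were planned. Of 1700 values of genes selected for naming under alternatives other than leaving out 1 library, 1651 kept direction and side of the threshold, 3 lost a call, 20 gained 1 and 26 reversed. The cause of the changes was not tested. Depth limits named genes below 5 CPM, and a lone escalating library, where 1 was left out, was assumed to vary like the other groups.

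Gene counts with DESeq2 were 2, 6, 11, 1, 7, 12 and 2 in the order non-escalating against saline, escalating against saline, escalating against non-escalating, non-escalating against saline withdrawal, saline withdrawal against saline, non-escalating withdrawal against none and the interaction, and 2950 for immunopurified against input. With no low-count filter they were 2 for escalating against saline (Preb and Gm7854) and 1 against non-escalating (Gm7854). With reads outside genes as a covariate they were 2 for escalating against saline (Preb and Gm7854) and 4 against non-escalating (Preb, Usp27x, Srgap1 and Gm7854). Gm7854 falls outside the naming rule and was chosen after its values were seen. With the replicate block the gene count stayed 0 in all 7 comparisons, and same-number pairs showed no sign of pairing in a check that could miss it. Leaving out each library gave 0 to 2 genes for escalating against saline, 0 to 6 for escalating against non-escalating, 241 to 1548 for immunopurified against input and 0 to 0 for the others.

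List counts fell to 0 with an estimated correlation and with fry in all comparisons of immunopurified libraries, and to 4 with an estimated correlation for immunopurified against input (10 with fry). For non-escalating intake against saline they were 0 with the replicate block, 0 with the non-neuronal score and 5 with reads outside genes. For escalating intake reads outside genes gave 1 against saline and 4 against non-escalating intake, and the replicate block 1 in the latter. For non-escalating against saline withdrawal, 14 were called without libraries above 50%, 4 in set B only and 27 in set A only. For saline withdrawal against saline, 13 were called with reads outside genes and 9 without libraries above 50%. The replicate block gave 5 for non-escalating withdrawal against none. The interaction had 7 with the non-neuronal score and 1 without libraries above 50%. Leaving out each library gave 0 to 14 (non-escalating against saline), 1 to 16 (escalating against saline), 1 to 5 (against non-escalating), 16 to 25 (non-escalating against saline withdrawal), 14 to 22 (saline withdrawal against saline), 4 to 19 (non-escalating withdrawal against none), 1 to 18 (interaction) and 11 to 14 (immunopurified against input).

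Some log2 fold changes reversed. In non-escalating against saline, reads outside genes gave Drd2 -0.18, Penk -0.19, Chat -0.16 and Adora2a -0.48. Adora2a was -0.01 with RLE factors, -0.01 with DESeq2, -0.11 with voom, -0.085 with the replicate block and -0.072 with the non-neuronal score. In set B only, non-escalating against saline withdrawal gave Drd2 -0.049 and Adora2a -0.23. In saline withdrawal against saline, Drd2 was 0.008 with reads outside genes. Without libraries above 50% Drd2 was 0.61, Adora2a 0.38 and Rasd2 0.23. In non-escalating withdrawal against none, Drd2 was -0.25 with voom and -0.14 with no set term, and Drd1 was 0.15 with no set term. There the fit of the compared groups alone gave Adora2a 0.25, Penk 0.061 and Drd1 0.031, reads outside genes gave Adora2a 0.36 and Penk 0.24, and leaving out libraries above 50% gave Adora2a 0.52, Penk 0.34 and Drd1 0.19.

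Leaving out each library reversed Drd2 (-0.084 to 0.54), Adora2a (-0.18 to 0.20), Drd1 (-0.20 to 0.77) and Chat (-0.21 to 0.76) in non-escalating against saline. It reversed Ttc27 (-2.14 to 4.75), Drd2 (-0.45 to 1.39) and Chat (-0.27 to 1.26) in escalating against saline. The same held for Ttc27 (-1.70 to 5.19), Drd2 (-0.71 to 1.12), Penk (-0.16 to 0.51) and Chat (-0.32 to 1.02) in escalating against non-escalating. It reversed Drd2 in saline withdrawal against saline (-0.57 to 0.10). Reversals also came for Rundc1 (-2.87 to 0.21), Drd2 (-0.24 to 0.39), Adora2a (-0.41 to 0.062), Penk (-0.38 to 0.009) and Drd1 (-0.26 to 0.046) in non-escalating withdrawal against none, and Chat (-0.27 to 0.79) and Vwf (-2.72 to 0.13) in the interaction.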

Other observations

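No explanation was tested in this part, and its values were chosen after the data were seen.

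Libraries also differed in the ribosomal RNA precursor Rn45s, whose share of gene counts ran from 0.406% in the saline input to 10.1% in non-escalating replicate 1. In set B it was 3.28% ± 1.44 (SD, n = 5) in non-escalating withdrawal and 7.56% ± 0.537 (SD, n = 3) in saline withdrawal (exact permutation p = 0.0179, two-sided, the smallest that 5 against 3 libraries allow). In set A it was 5.84% ± 1.91 (n = 4) against 2.97% ± 2.62 (n = 2, exact permutation p = 0.2), and over both sets 4.42% ± 2.05 (n = 9) against 5.73% ± 2.86 (n = 5, exact permutation p = 0.335, adjusted p = 0.75 over the library measures).

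Gpr6, an orphan receptor of indirect-pathway neurons, was at 104 ± 37.5 CPM (SD, n = 3) in saline, 137 ± 53.7 CPM (n = 4) in non-escalating, 114 ± 28.6 CPM (n = 2) in escalating, 47.1 ± 23.3 CPM (n = 5) in saline withdrawal and 104 ± 75 CPM (n = 9) in non-escalating withdrawal libraries. It was at 12.7 to 50.1 CPM in the inputs. Slc17a7, the vesicular glutamate transporter of cortical neurons, was at 8.59 ± 14.8 CPM (n = 3) in saline and 9.04 ± 8.80 CPM (n = 9) in non-escalating withdrawal libraries. Its inputs were at 109 (saline), 187 (non-escalating) and 2.95 CPM (saline withdrawal). Both were chosen after their values were seen.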
